A study of Mus musculus with 24 samples.

How the data were processed

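The study deposited RNA-seq values of 24 libraries from mouse marrow-derived mesenchymal stem cells grown in MEM alpha from cryopreserved stocks of at most 10 passages. Cells were undifferentiated, in osteogenic medium for 7 or 15 days or in adipogenic medium for 7 days, and each state had 3 libraries with 100 nM 1,25(OH)2D3 for 24 hours and 3 with ethanol vehicle. Per the labels, total RNA was extracted with TRI-Reagent and lithium chloride, treated with DNase, depleted of ribosomal RNA (RiboMinus) and made into directional libraries (ScriptSeq). Reads were aligned to mm9 with TopHat (no version given). Quantification tool, transcript annotation and any filter are not stated.

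The deposited values are RPKM, computed by the authors, with 1 value per transcript and 3 decimals. Each library lists 30795 transcripts under 25410 gene symbols, 3470 of them with several transcripts, which were summed by symbol. The 40 transcripts (25 symbols) whose symbols had been turned into dates were left out, leaving 25385 genes. Only RPKM was used, and no read counts or raw reads were available. Reads per library were estimated from the step between whole-number multiples among 150 low values of single-transcript olfactory receptor genes of 900 to 1000 bases, and 89.3 to 98.7% of these values lay within 0.1 of a whole number of reads. The estimate is 7.12 to 46.8 M reads, so 3 reads on a transcript of 1 kilobase correspond to 0.0642 to 0.421 RPKM. The sum of RPKM is not a fixed total and was 532416 to 773353 by library. Libraries of a group correlated at 0.926 to 0.993, and 0 pairs of libraries were identical.

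Genes with at least 1 RPKM in at least 3 libraries (21097) were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1): a linear model with the 8 groups over all 24 libraries, empirical Bayes with trend and robust options, Benjamini-Hochberg adjustment within each comparison and a threshold of adjusted p < 0.05. In all, 5 comparisons used vehicle libraries (osteogenic days 7 and 15 and adipogenic day 7 against day 0, osteogenic day 15 against 7, adipogenic against osteogenic day 7). Another 4 set VD3 against vehicle in each state, and 4 tested the difference of that effect between states. The 31 gene lists, from general knowledge, were tested with camera of limma, adjusted over the lists of a comparison. It compares a list with all other tested genes. With a correlation estimated from the data it called 81 of 390 tests of lists with at least 4 measured genes (137 with 0.01 preset). List calls in the report use the estimate, and lists passing only with the preset one show both values. Counts of list members are given over all genes and adjusted over the list alone. Preparation and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

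Groups, comparisons, tests, gene lists, alternative settings and the rule for naming genes were set before the data were examined. The rule names the 6 largest rises and 6 largest falls by log2 value with at least 5 RPKM in the higher group and no overlap between libraries, without predicted, clone, small RNA and histone genes. It adds called members with the largest changes in each list described, of which up to 3 are printed, not always the largest, 10 genes in every comparison (Vdr, Cyp24a1, Runx2, Cebpb, Cebpa, Pparg, Tnfsf11, Spp1, Alpl and Fabp4), and 3 genes each way for each difference of VD3 effects. Which lists are described, and the number of 3, were chosen after the results were seen. Genes listed as changed in all 4 states were chosen after their values were seen, among those the rule names elsewhere. Some genes that the rule names are not reported here, and counts include them.

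Alternatives chosen beforehand were a pseudocount of 0.1, no filter, a filter at 5 RPKM, rescaling by median ratio, quantile normalization, a replicate term, plain empirical Bayes, a fit on only the libraries compared, VD3-treated in place of vehicle libraries, and leaving out each library in turn. Others were chosen after seeing the data: the largest transcript in place of the sum, subtraction of a background equal for all genes, subtraction of a background matched on GC content in 20 bins (16017 genes tested), genes with a mean of at least 20 RPKM (3503 tested), and VD3-treated libraries with day 0 VD3 replicate 2 as the lone day 0 library. GC content came from a GENCODE M21 annotation, which is on another genome build than the deposited values, and was found for 90.9% of genes by symbol. Genes were located by symbol only, and no genome coordinates are reported. Where 1 library is left in a group, it is assumed to vary like the other groups.

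The test was run on 21097 simulated genes, with 200 changed of at least 5 RPKM (lower ones untested). At 2-fold it recovered 82.0, 86.0, 84.0 and 88.0% of 50 genes for VD3 (day 0, osteogenic days 7 and 15, adipogenic day 7). Against day 0, osteogenic and adipogenic day 7 had 72.0 and 80.0%, and a difference of VD3 effects 70.0%. At 1.5-fold the 7 values were 26.0 to 70.0%, and false calls were 2.48 to 7.47% of calls. Of 30 lists, only the 1 shifted by 0.5 log2 was called. Nothing else was changed, so false calls from a background differing between groups were not measured.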

Results

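RNA was sequenced from mouse marrow-derived mesenchymal stem cells (MSC), multipotent stromal cells that can form osteoblasts and adipocytes. The 24 libraries formed 8 groups of 3: undifferentiated (day 0), osteogenic medium for 7 or 15 days and adipogenic medium for 7 days. Each state had ethanol vehicle or 100 nM 1,25(OH)2D3 for 24 hours. 1,25(OH)2D3 (VD3) is the hormonal form of vitamin D and the ligand of the nuclear receptor Vdr. Values below are mean RPKM ± SD with n = 3 libraries a group, and a log2 value is the difference on the log2(RPKM + 1) scale, which understates changes of low genes. A gene rose or fell where its adjusted p in limma was below 0.05. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples. Genes named as the largest changes had no overlap between the 3 and 3 libraries. Depth estimated from low values was 7.12 to 46.8 M reads a library. From 11943 to 20956 genes of 25385 had at least 1 RPKM, and 7SK RNA (Rn7sk) was the most abundant gene in every library, with 7.94 to 26.5% of the total.

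Among the day 0 libraries, 5 stood apart from the rest in their signal on olfactory, vomeronasal and taste receptor genes, 1491 genes of families normally silent outside sensory tissue. Their median in those 5 libraries was 3.39 to 4.95 RPKM, and in the other 19 libraries 0.208 to 1.30 RPKM, with 0.458 RPKM in the remaining day 0 library, VD3 replicate 2. The same 5 libraries had 7.12 to 11.01 M estimated reads, against 11.8 to 46.8 M in the other 19. By group the median was 4.21 ± 0.721 RPKM in day 0 vehicle, 2.77 ± 2.07 in day 0 VD3 and between 0.334 ± 0.0838 and 0.976 ± 0.425 in the differentiated groups. Of 1469 such genes tested, 1446 were lower on osteogenic day 7 than at day 0, 1455 on osteogenic day 15, 1425 on adipogenic day 7 and 107 after VD3 at day 0. This signal (the background below) moved with each comparison to day 0, where its fall can favour higher list calls.

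**Figure D1:**
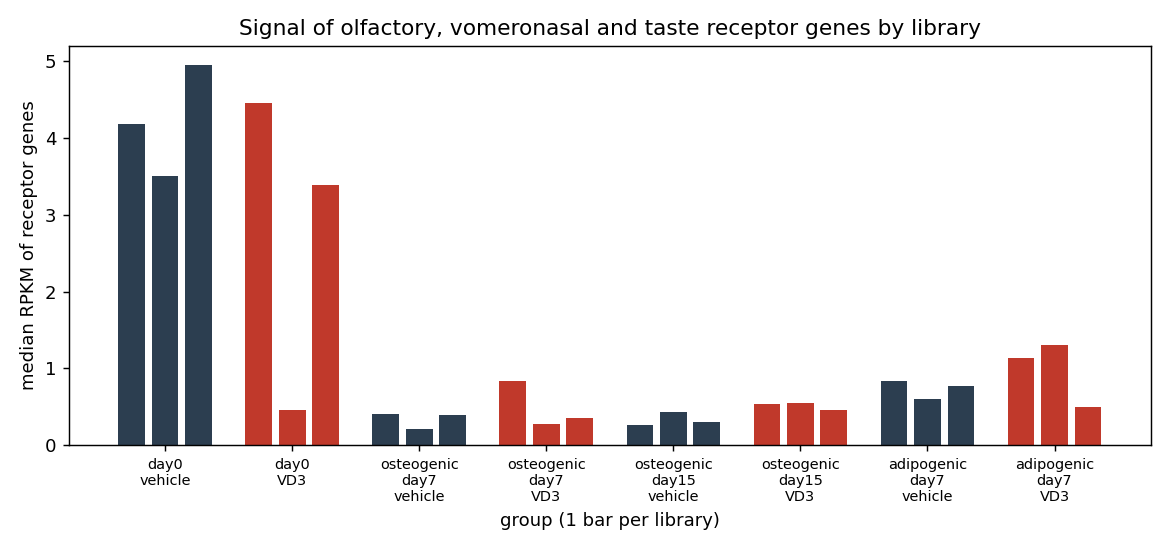
Median RPKM of olfactory, vomeronasal and taste receptor genes, with 1 bar for each of the 24 libraries, vehicle dark and VD3 red. In 5 day 0 libraries the median lies between 3.39 and 4.95 RPKM, and in the other 19 between 0.208 and 1.30.

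Osteogenic medium (beta-glycerophosphate and ascorbic acid) for 7 days was compared with day 0 among vehicle libraries, which asks what changed toward bone. No undifferentiated library has a later day, so medium and days in culture cannot be told apart against day 0. Genes of mineralizing bone cells were among the largest rises. Dmp1, a phosphoprotein of mineralizing osteocytes, reached 178 ± 10.0 against 1.59 ± 0.397 RPKM at day 0, and Ibsp, the bone sialoprotein that binds mineral, 264 ± 11.9 against 9.55 ± 0.514. The other large rises were the alarmin cytokine Il33 (66.2 ± 11.8 against 1.33 ± 0.139), the secreted Wnt antagonist Sfrp4 (65.5 ± 5.65 against 3.71 ± 0.455), the small proteoglycan Dcn (81.7 ± 8.38 against 5.47 ± 1.39) and the hyaluronan synthase Has2 (103 ± 12.5 against 11.1 ± 0.202). Alpl, the alkaline phosphatase needed for mineralization, rose from 5.44 ± 0.992 to 18.1 ± 2.92 RPKM.

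Of the osteoblast genes 14 rose and 2 fell of 21 (15 and 2 adjusted over the list alone), with camera adjusted p = 0.00162. The osteocalcin genes Bglap2 (23.6 ± 3.37 against 3.44 ± 1.23 RPKM) and Bglap (29.4 ± 2.65 against 4.59 ± 1.45) rose, and Spp1, the matrix protein osteopontin, was at 1655 ± 292 against 1971 ± 136. Of the osteocyte genes 5 rose and 1 fell of 8 (5 and 1 adjusted over the list alone), with adjusted p = 0.00985. They include the phosphate-regulating endopeptidase Phex (26.1 ± 3.91 against 3.46 ± 0.829) and podoplanin, Pdpn (36.9 ± 2.60 against 9.53 ± 1.10). Of the mineralization and phosphate handling genes 7 rose and 3 fell of 12 (7 and 3 adjusted over the list alone), with adjusted p = 0.0114. Of the fibrillar and associated matrix genes 16 rose and 4 fell of 25 (16 and 4 adjusted over the list alone), with adjusted p = 0.00114, and beside Dcn the glycoprotein Tnc (96.5 ± 3.68 against 12.2 ± 0.512) rose. Smooth muscle and pericyte markers moved the same way: 6 rose and 1 fell of 10 (6 and 1 adjusted over the list alone), adjusted p = 0.0241. Among them were Rgs5 (11.4 ± 2.32 against 2.52 ± 0.851) and Tagln (128 ± 2.85 against 51.9 ± 5.09). Of the immediate early and stress genes 6 rose and 0 fell of 13 (6 and 0 adjusted over the list alone), with adjusted p = 0.00162. They were led by Ier3 (21.01 ± 1.99 against 5.99 ± 1.85) and Jun (36.9 ± 5.09 against 15.5 ± 2.07). Of the cholesterol synthesis genes 10 rose and 2 fell of 17 (10 and 2 adjusted over the list alone), with adjusted p = 0.00162. Hsd17b7 (39.7 ± 4.76 against 20.1 ± 0.804) rose and the sterol sensor partner Insig1 (119 ± 3.10 against 199 ± 8.05) fell.

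Adipocyte genes were lower on osteogenic day 7: 0 rose and 17 fell of 21 (0 and 17 adjusted over the list alone), adjusted p = 0.0392. The adipogenic transcription factors Cebpa (20.7 ± 4.59 against 72.4 ± 11.7 RPKM) and Pparg (19.1 ± 3.08 against 32.0 ± 2.74), the lipid droplet protein Plin4 (13.1 ± 1.92 against 69.3 ± 3.11) and the fatty acid carrier Fabp4 (16.2 ± 3.68 against 51.0 ± 10.4) fell. All 16 interferon-responsive genes tested fell, as did 16 adjusted over the list alone. Examples are Isg15 (5.95 ± 1.65 against 37.9 ± 4.67) and Ifi44 (4.61 ± 1.05 against 29.4 ± 4.46). Their list test had adjusted p = 0.143 with an estimated correlation and 1.14e-05 with a preset one, and 0.0161 among VD3-treated libraries (0.00201 with replicate 2 as their lone day 0 library). The largest falls were the granzyme Gzme (8.07 ± 1.99 against 161 ± 9.65), Srsx (8.58 ± 1.40 against 133 ± 36.3) and Speer7-ps1 (3.17 ± 1.54 against 53.3 ± 4.10). Next came the mast cell protease Mcpt8 (3.46 ± 0.535 against 58.3 ± 7.61), Hrnr (1.55 ± 0.0265 against 32.7 ± 6.02) and Otor (0.227 ± 0.25 against 14.7 ± 4.65). Vdr (1.18 ± 0.485 against 2.46 ± 0.0407) and its target Cyp24a1, the enzyme that inactivates VD3 (0.109 ± 0.0960 against 1.62 ± 0.661), were below the background median of 4.21 ± 0.721 RPKM of the day 0 vehicle libraries. The osteoblast transcription factor Runx2 (7.62 ± 0.101 against 5.72 ± 1.26, adjusted p = 0.0600), the osteoclast-inducing cytokine Tnfsf11 (1.16 ± 0.692 against 1.84 ± 0.274, adjusted p = 0.114) and the transcription factor Cebpb (22.4 ± 2.95 against 25.7 ± 14.5, adjusted p = 0.886) did not pass the test.

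In all, 2874 genes were higher and 10636 lower of 21097 tested (254 and 7263 at 2-fold or more), and the median of all genes was -0.46 log2. The higher share of 21.3% became 43.4% with median-ratio rescaling and 59.4% with quantile normalization, which shifted the median by 0.33 and 0.81 log2. After subtraction of a background matched on GC content, 4967 were higher and 3745 lower of 16017 tested. With a background equal for all genes subtracted (the equal subtraction below) these were 8710 and 1451, and with a filter at 5 RPKM 2650 and 2768. The adipocyte list was called after the GC-matched subtraction (0 rose and 8 fell, adjusted p = 0.0379) and among VD3-treated libraries with replicate 2 as the lone day 0 library (0.00983), but not with median-ratio rescaling (adjusted p = 0.0947), quantile normalization (0.252), among VD3-treated libraries (0.0921) or without day 0 vehicle replicate 2 (0.0534) or osteogenic day 7 vehicle replicate 3 (0.0515). In that replicate 2 setting abundant noncoding RNAs, a sign of RNA quality, were called lower too (1 rose and 4 fell of 10, 0.0313). The cholesterol and mineralization lists were not called after the GC-matched subtraction (0.0570 and 0.0651), with median-ratio rescaling (0.206 and 0.0970) or with quantile normalization (0.0734 for both). With median-ratio rescaling the matrix (0.107), immediate early (0.0925) and smooth muscle (0.0527) calls ended too. Vdr turned to 0.49 with quantile normalization, Tnfsf11 to 0.88 after the GC-matched subtraction, and Speer7-ps1 and Hrnr to 0.49 and 0.50 log2 among VD3-treated libraries with replicate 2 as the lone day 0 library. The log2 value of Spp1 was -0.26 and turned to 0.17 with median-ratio rescaling. Its call was lost without day 0 vehicle replicate 1 (-0.24) or 3 (-0.23), or osteogenic day 7 vehicle replicate 1 (-0.25) or 3 (-0.15). None of these list calls held in the fit on only the libraries compared, the narrow fit below (lowest adjusted p = 0.0641), and with the equal subtraction the adipocyte call alone did (0.0276). Runx2 passed without day 0 vehicle replicate 1 (0.48), Cebpb without day 0 vehicle replicate 3 (-0.48) and Tnfsf11 without osteogenic day 7 vehicle replicate 1 (-0.68).

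After 15 days in osteogenic medium, Ibsp reached 596 ± 40.1 against 9.55 ± 0.514 RPKM at day 0 and Il33 219 ± 22.8 against 1.33 ± 0.139. The BMP antagonist Grem1 (45.3 ± 4.03 against 0.866 ± 0.550), the natriuretic peptide Nppc (24.4 ± 0.971 against 0.155 ± 0.139), Dcn (118 ± 7.38 against 5.47 ± 1.39) and the coagulation factor subunit F13a1 (51.9 ± 1.504 against 2.09 ± 0.573) were the other largest rises. Immediate early and stress genes rose: 11 rose and 1 fell of 13 (11 and 1 adjusted over the list alone), adjusted p = 0.00120. They include the stress-induced pseudokinase Trib3 (26.6 ± 4.91 against 1.39 ± 0.214) and the transcription factor Ddit3 (CHOP, 123 ± 37.0 against 17.8 ± 4.44). Of the osteoblast genes 12 rose and 3 fell of 21 (12 and 3 adjusted over the list alone), with adjusted p = 0.0327. They include the parathyroid hormone receptor Pth1r (6.95 ± 0.340 against 0.874 ± 0.573), the transcription factor Atf4 (302 ± 27.4 against 70.7 ± 2.58) and Alpl (24.7 ± 5.88 against 5.44 ± 0.992). Of the oxidative phosphorylation and citrate cycle genes 10 rose and 0 fell of 18 (10 and 0 adjusted over the list alone), with adjusted p = 0.0327. Sdhb (35.9 ± 1.80 against 20.6 ± 0.987) rose most. Smooth muscle and pericyte markers (2 rose and 2 fell of 10 (2 and 2 adjusted over the list alone), adjusted p = 0.721) were called higher among VD3-treated libraries (0.0448, and 0.0424 with replicate 2 as their lone day 0 library).

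Fat genes were low at this time. Adiponectin, Adipoq, fell to 0.895 ± 0.205 RPKM from 26.4 ± 1.29, Plin4 to 6.23 ± 0.672 from 69.3 ± 3.11, Fabp4 to 5.79 ± 0.781 from 51.0 ± 10.4, Cebpa to 6.54 ± 0.492 from 72.4 ± 11.7 and Pparg to 7.74 ± 1.246 from 32.0 ± 2.74. Of the adipocyte genes 0 rose and 17 fell of 21 (1 and 19 adjusted over the list alone), while the list test had adjusted p = 0.0704 with an estimated correlation and 0.000313 with a preset one. Of the interferon-responsive genes 0 rose and 15 fell of 16 (0 and 15 adjusted over the list alone), with adjusted p = 0.267 with an estimated correlation and 2.19e-05 with a preset one. Among them were Ifi44 (1.84 ± 0.937 against 29.4 ± 4.46) and Ifit3 (36.1 ± 6.39 against 242 ± 63.2). The largest falls were Gzme (1.48 ± 0.175 against 161 ± 9.65), the interleukin-1 receptor antagonist Il1rn (1.48 ± 0.654 against 105 ± 8.19), and the interferon-induced Ifi27l2a (0.562 ± 0.810 against 46.1 ± 9.87). Next came Mcpt8 (1.13 ± 0.914 against 58.3 ± 7.61), the anion transporter Slc26a7 (0.446 ± 0.329 against 38.2 ± 4.80) and the thioredoxin inhibitor Txnip (1.18 ± 0.459 against 55.8 ± 4.94). Spp1 fell to 854 ± 17.3 from 1971 ± 136. Vdr (0.863 ± 0.0445 against 2.46 ± 0.0407), Cyp24a1 (0.218 ± 0.266 against 1.62 ± 0.661) and Tnfsf11 (0.760 ± 0.229 against 1.84 ± 0.274) were again under the day 0 background median. Runx2 (6.28 ± 1.08 against 5.72 ± 1.26, adjusted p = 0.533) and Cebpb (33.6 ± 2.86 against 25.7 ± 14.5, adjusted p = 0.0707) did not pass the test.

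The counts were 3692 higher and 11260 lower (533 and 7557 at 2-fold or more), with a median of -0.55 log2 over all genes. Higher genes were 24.7% of calls, which became 40.9% with median-ratio rescaling and 58.6% with quantile normalization (median shifts 0.31 and 0.83), and 5461 were higher and 4407 lower after the GC-matched subtraction, 8538 and 1774 after the equal one and 3474 and 3369 with a filter at 5 RPKM. The osteoblast list was not called after that subtraction (adjusted p = 0.114) or with quantile normalization (0.0932). The stress list was not called with median-ratio rescaling (0.0510) or quantile normalization (0.0932). The oxidative phosphorylation call ended with both rescalings (0.408 and 0.613), after the subtraction (0.267), among VD3-treated libraries (0.271) and without osteogenic day 15 vehicle replicate 1 (0.0583) or day 0 vehicle replicate 2 (0.0506). The adipocyte and interferon lists were called among VD3-treated libraries (0.0448 for both, and 0.0106 and 0.0117 with replicate 2 as their lone day 0 library), the first also after the subtraction (adjusted p = 0.0339) and without day 0 vehicle replicate 1 (0.0488), and Cebpb passed without day 0 vehicle replicate 2 (0.93 log2). None of the 3 list calls held in the narrow fit (adjusted p = 0.163 for each) or with the equal subtraction (lowest 0.376). Vdr turned to 0.35 and Tnfsf11 to 0.49 log2 with quantile normalization.

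Adipogenic medium (insulin, indomethacin and dexamethasone) for 7 days was compared with day 0, which asks what changed toward fat. The 6 largest rises were all genes of fat cells. Fabp4 reached 22526 ± 902 against 51.0 ± 10.4 RPKM at day 0, the lipid droplet protein Cidec 2260 ± 92.2 against 0.929 ± 0.555 and the fatty acid transporter Cd36 1356 ± 80.6 against 1.82 ± 0.656. The adipokine Cfd (adipsin) reached 514 ± 33.2 against 0.301 ± 0.294, the glycerol 3-phosphate dehydrogenase Gpd1 379 ± 24.7 against 1.74 ± 0.839 and the lipid droplet protein Plin1 192 ± 8.08 against 0.522 ± 0.211. The adipogenic regulators Pparg (119 ± 8.53 against 32.0 ± 2.74) and Cebpa (157 ± 15.0 against 72.4 ± 11.7) rose with them. Of the adipocyte genes 19 rose and 2 fell of 21 (19 and 2 adjusted over the list alone), with adjusted p = 2.83e-06.

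Of the fatty acid and triglyceride synthesis genes 14 rose and 1 fell of 16 (14 and 1 adjusted over the list alone), with adjusted p = 1.07e-06. The desaturase Scd1 reached 9563 ± 367 against 136 ± 11.7 RPKM. All 18 oxidative phosphorylation and citrate cycle genes rose, as did 18 adjusted over the list alone, with adjusted p = 2.83e-06. They include cytochrome c, Cycs (486 ± 36.0 against 45.2 ± 6.42), and the citrate cycle enzyme Idh3a (181 ± 8.82 against 19.7 ± 2.50). Of the glucocorticoid-responsive genes 11 rose and 1 fell of 14 (11 and 1 adjusted over the list alone), with adjusted p = 7.04e-06. The first in size were the receptor co-chaperone Fkbp5 (139 ± 7.81 against 4.73 ± 0.468), glutamine synthetase, Glul (345 ± 24.9 against 17.7 ± 2.11), and Zbtb16 (24.9 ± 1.48 against 1.07 ± 0.609). Dexamethasone, a glucocorticoid, was in the adipogenic medium only, per the labels.

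Proliferation genes fell: 0 rose and 24 fell of 26 (0 and 24 adjusted over the list alone), adjusted p = 3.82e-05. Examples are the ribonucleotide reductase subunit Rrm2 (2.02 ± 0.376 against 27.6 ± 4.21 RPKM) and cyclin A2, Ccna2 (2.30 ± 0.202 against 26.2 ± 1.14). Of the marrow stromal and MSC markers 1 rose and 11 fell of 14 (1 and 11 adjusted over the list alone), with adjusted p = 0.0256. They include the chemokine Cxcl12 (55.8 ± 7.60 against 943 ± 15.7) and the growth factor receptors Pdgfrb (6.15 ± 0.487 against 53.9 ± 1.89) and Pdgfra (8.37 ± 0.450 against 70.3 ± 2.89). Of the matrix genes 4 rose and 21 fell of 25 (4 and 21 adjusted over the list alone), with adjusted p = 0.0381. Fibrillin, Fbn1 (4.98 ± 0.429 against 62.8 ± 3.21), changed most. Of the interferon-responsive genes 1 rose and 15 fell of 16 (1 and 15 adjusted over the list alone), with adjusted p = 0.311 with an estimated correlation and 0.00105 with a preset one; Ifit3 (26.8 ± 6.19 against 242 ± 63.2) and Bst2 (10.3 ± 2.00 against 94.5 ± 14.9) fell. The largest falls were the Wnt antagonist Sfrp1 (3.39 ± 0.549 against 232 ± 13.2), the retinoic acid-forming Aldh1a2 (1.23 ± 0.198 against 75.2 ± 1.42), and Mcpt8 (0.836 ± 0.426 against 58.3 ± 7.61). They also included the mineralization inhibitor Mgp (13.8 ± 3.38 against 459 ± 20.3), the smooth muscle actin Actg2 (1.14 ± 0.445 against 63.3 ± 2.42) and Emp1 (31.5 ± 2.45 against 840 ± 43.8). Spp1 fell to 134 ± 11.3 from 1971 ± 136 and Runx2 to 2.38 ± 0.569 from 5.72 ± 1.26, while Alpl rose to 17.3 ± 2.58 from 5.44 ± 0.992 and Cebpb to 37.3 ± 2.82 from 25.7 ± 14.5. Vdr (0.779 ± 0.0533 against 2.46 ± 0.0407), Cyp24a1 (0.252 ± 0.135 against 1.62 ± 0.661) and Tnfsf11 (0.170 ± 0.107 against 1.84 ± 0.274) lay under the day 0 background median.

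The counts were 2775 higher and 13814 lower (1099 and 8607 at 2-fold or more), with a median of -0.83 log2 over all genes. Of all calls 16.7% were higher, and this share became 36.4% with median-ratio rescaling and 51.0% with quantile normalization (median shifts 0.47 and 0.82), and 3763 were higher and 6696 lower after the GC-matched subtraction, 5511 and 3137 after the equal one and 2564 and 5608 with a filter at 5 RPKM. The matrix and MSC marker calls ended after that subtraction (adjusted p = 0.0525 and 0.0587), with median-ratio rescaling (0.407 and 0.215) and in the narrow fit (0.299 and 0.243). With the equal subtraction the adipocyte (0.000527) and oxidative phosphorylation (0.0135) calls alone held. Vdr turned to 0.17 log2 with quantile normalization, and Runx2 to 0.15 after the equal subtraction. The call of Cebpb (log2 0.67) was lost without day 0 vehicle replicate 3 (0.24) or adipogenic day 7 vehicle replicate 1 (0.61).

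Between osteogenic days 7 and 15, which asks what changed with longer culture, Trib3 and Ddit3 rose and lipid and matrix genes fell. Trib3 went to 26.6 ± 4.91 RPKM from 1.68 ± 0.516, Ddit3 to 123 ± 37.0 from 20.5 ± 2.39, and Nppc to 24.4 ± 0.971 from 4.07 ± 0.316. Grem1 went to 45.3 ± 4.03 from 8.94 ± 1.74, Tmem169 to 8.99 ± 1.66 from 1.15 ± 0.499 and the glycolytic mutase Pgam2 to 6.06 ± 0.362 from 0.710 ± 0.4997. The largest falls were Ifi27l2a (0.562 ± 0.810 against 12.1 ± 3.65 on day 7), Adipoq (0.895 ± 0.205 against 12.1 ± 0.656), and Sfrp1 (9.62 ± 0.426 against 61.4 ± 5.18). They also took in Il1rn (1.48 ± 0.654 against 13.2 ± 2.07), the dipeptidase Dpep1 (1.44 ± 0.202 against 12.2 ± 1.80) and Txnip (1.18 ± 0.459 against 10.4 ± 0.322). The background median was 0.337 ± 0.112 RPKM on day 7 and 0.334 ± 0.0838 on day 15.

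Of the cholesterol synthesis genes 0 rose and 15 fell of 17 (0 and 15 adjusted over the list alone), with adjusted p = 1.10e-05. Idi1 (21.1 ± 2.10 against 50.2 ± 6.42 RPKM) fell most. Fatty acid and triglyceride synthesis went the same way: 0 rose and 9 fell of 16 (1 and 9 adjusted over the list alone), adjusted p = 0.000742, and Scd1 (42.0 ± 1.95 against 111 ± 10.2) fell. Of the matrix genes 4 rose and 15 fell of 25 (4 and 17 adjusted over the list alone), with adjusted p = 0.000300. The collagen Col6a1 (91.0 ± 4.85 against 273 ± 19.4) fell most. Of the basement membrane genes 1 rose and 7 fell of 13 (1 and 8 adjusted over the list alone), with adjusted p = 0.000627. They were led by Col4a1 (22.5 ± 1.47 against 84.7 ± 3.11) and Col4a2 (17.3 ± 0.751 against 62.1 ± 0.317). Of the mineralization genes 0 rose and 7 fell of 12 (1 and 7 adjusted over the list alone), with adjusted p = 0.00354. Phex (6.55 ± 0.578 against 26.1 ± 3.91) fell most. Of the proliferation genes 0 rose and 12 fell of 26 (1 and 12 adjusted over the list alone), with adjusted p = 0.000300, and Rrm2 (11.5 ± 1.35 against 27.7 ± 1.08) fell. Among VD3-treated libraries this list was called the other way (5 rose and 2 fell, adjusted p = 0.0457). Glycolysis and hypoxia-responsive genes went up: 9 rose and 1 fell of 15 (9 and 1 adjusted over the list alone), adjusted p = 0.00165, and the glycolytic Eno1 (136 ± 17.8 against 67.2 ± 5.83) and Pgk1 (223 ± 28.3 against 128 ± 2.89) rose. The immediate early and stress list was not called (adjusted p = 0.0733, 0.0294 with a preset correlation) except without osteogenic day 15 vehicle replicate 2 (0.0288) or osteogenic day 7 vehicle replicate 3 (0.0284). The mineralization list loses its call among genes with a mean of at least 20 RPKM (0.0584).

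Cebpa (6.54 ± 0.492 against 20.7 ± 4.59 RPKM), Pparg (7.74 ± 1.246 against 19.1 ± 3.08), Fabp4 (5.79 ± 0.781 against 16.2 ± 3.68) and Spp1 (854 ± 17.3 against 1655 ± 292) fell further between the days. Alpl (24.7 ± 5.88 against 18.1 ± 2.92, adjusted p = 0.0902), Runx2 (6.28 ± 1.08 against 7.62 ± 0.101, 0.474), and Cebpb (33.6 ± 2.86 against 22.4 ± 2.95, 0.174) did not pass the test. Neither did Vdr (0.863 ± 0.0445 against 1.18 ± 0.485, 0.648), Cyp24a1 (0.218 ± 0.266 against 0.109 ± 0.0960, 0.889) and Tnfsf11 (0.760 ± 0.229 against 1.16 ± 0.692, 0.679). In all, 1449 genes were higher and 1364 lower (108 and 197 at 2-fold or more), with a higher share of 51.5% that became 40.7% (740 and 1078 genes) with median-ratio rescaling. That rescaling ended the calls of the matrix (adjusted p = 0.0737), glycolysis (0.0785) and fatty acid (0.0898) lists. None of the list calls held in the narrow fit (lowest 0.0680), and with the equal subtraction the cholesterol, matrix, basement membrane and glycolysis calls alone did (0.0394 each). Alpl passed without osteogenic day 7 vehicle replicate 3 (0.53) or osteogenic day 15 vehicle replicate 2 (0.54).

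Adipogenic and osteogenic cells were compared at day 7, which asks how the fates differ. Cidec stood at 2260 ± 92.2 against 0.0837 ± 0.0957 RPKM in osteogenic cells, Fabp4 at 22526 ± 902 against 16.2 ± 3.68, and Cd36 at 1356 ± 80.6 against 0.421 ± 0.280. Cfd was at 514 ± 33.2 against 0.110 ± 0.107, the serine palmitoyltransferase subunit Sptlc3 at 437 ± 17.3 against 0.248 ± 0.0455 and Gpd1 at 379 ± 24.7 against 0.362 ± 0.104. On the osteogenic side the largest differences were Aldh1a2 (1.23 ± 0.198 against 300 ± 16.2 in osteogenic cells), Dmp1 (1.82 ± 0.374 against 178 ± 10.0), and Actg2 (1.14 ± 0.445 against 119 ± 4.77). Next came Sfrp4 (0.194 ± 0.0868 against 65.5 ± 5.65), Il33 (0.637 ± 0.0890 against 66.2 ± 11.8) and the collagen Col8a1 (9.38 ± 0.460 against 297 ± 16.1). Of the adipocyte genes 19 were higher and 0 lower in adipogenic cells of 21 (19 and 0 adjusted over the list alone), with adjusted p = 6.02e-06. For the osteoblast genes these counts were 1 and 16 of 21 (1 and 16 adjusted over the list alone), with adjusted p = 0.0123. The collagen chains Col1a1 (9.50 ± 2.21 against 186 ± 19.98) and Col1a2 (57.0 ± 1.73 against 731 ± 53.5) and Spp1 (134 ± 11.3 against 1655 ± 292) were lower in adipogenic cells.

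Matrix genes separated the fates further: 2 higher and 22 lower of 25 (2 and 23 adjusted over the list alone), adjusted p = 7.38e-05. Among them were Fbn1 at 4.98 ± 0.429 against 170 ± 6.33 RPKM and the collagen Col3a1 at 33.6 ± 0.131 against 813 ± 95.6. Of the Wnt pathway targets and antagonists 0 were higher and 14 lower of 20 (0 and 14 adjusted over the list alone), with adjusted p = 0.00449. Sfrp1 was at 3.39 ± 0.549 against 61.4 ± 5.18. Mineralization genes were 1 higher and 8 lower of 12 (1 and 8 adjusted over the list alone), adjusted p = 0.00482. The osteocyte list had 0 higher and 5 lower of 8 (0 and 5 adjusted over the list alone), with adjusted p = 0.0128. MSC markers were 1 higher and 12 lower of 14 (1 and 12 adjusted over the list alone), adjusted p = 0.000267, and Pdgfra was at 8.37 ± 0.450 against 80.2 ± 2.38. All 26 proliferation genes were lower, as were 26 adjusted over the list alone, adjusted p = 2.79e-06, and Rrm2 was at 2.02 ± 0.376 against 27.7 ± 1.08. All 18 oxidative phosphorylation genes (18 adjusted over the list alone) and 14 of 16 fatty acid genes (14 adjusted over the list alone, 1 lower) were higher, with adjusted p = 3.61e-05 and 6.48e-06. Glucocorticoid-responsive genes were 12 higher and 2 lower of 14 (12 and 2 adjusted over the list alone), adjusted p = 0.000125, and glycolysis genes 9 and 2 of 15 (10 and 2 adjusted over the list alone), adjusted p = 0.00755 (0.112 with median-ratio rescaling).

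Pparg (119 ± 8.53 against 19.1 ± 3.08 RPKM), Cebpa (157 ± 15.0 against 20.7 ± 4.59) and Cebpb (37.3 ± 2.82 against 22.4 ± 2.95) were higher in adipogenic cells, and Runx2 (2.38 ± 0.569 against 7.62 ± 0.101) and Tnfsf11 (0.170 ± 0.107 against 1.16 ± 0.692) lower. Alpl (17.3 ± 2.58 against 18.1 ± 2.92, adjusted p = 0.820), Vdr (0.779 ± 0.0533 against 1.18 ± 0.485, 0.279) and Cyp24a1 (0.252 ± 0.135 against 0.109 ± 0.0960, 0.572) did not pass the test. In all, 2626 genes were higher and 5351 lower in adipogenic cells (1219 and 2221 at 2-fold or more). The higher share of 32.9% became 46.2% with median-ratio rescaling (median shift 0.14 log2) and 43.6% with quantile normalization. Cebpb (log2 0.72) lost its call without osteogenic day 7 vehicle replicate 1 (0.68) or 2 (0.65) or adipogenic day 7 vehicle replicate 1 (0.66), 2 (0.74) or 3 (0.75), and Tnfsf11 (log2 -0.84) without osteogenic day 7 vehicle replicate 1 (-0.60). Vdr passed without osteogenic day 7 vehicle replicate 2 (-0.47). The osteoblast call ended in the narrow fit (adjusted p = 0.0658), and with the equal subtraction the adipocyte (1.25e-05), oxidative phosphorylation (0.00151) and glucocorticoid (0.0272) calls alone held. Cebpb turned to -0.32 log2 among VD3-treated libraries.

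Changes from day 0 overlapped between the fates, which share days in culture. Among genes called in both comparisons, 931 were higher on osteogenic day 7 and on adipogenic day 7 (378 expected from the counts if independent), 9331 lower in both (6964 expected) and 1581 opposite. After the GC-matched subtraction these were 1913 (1167 expected), 3095 (1566) and 1494. Both comparisons use the same 3 day 0 vehicle libraries, and the lower sets include most background genes. Unchanged simulated groups that shared a simulated control group gave a correlation of 0.528 across genes in 20 draws, against 0.533 for the pair, so the correlation alone does not set the pair apart. The covariance was 0.0359, against 0.484, and the draws, in which no gene was changed, had 0 shared calls. After the subtraction the correlation was 0.477, against 0.542 simulated. The 3 controls were not split between the comparisons, since 1 of the parts would hold 1 library.

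**Figure D2:**
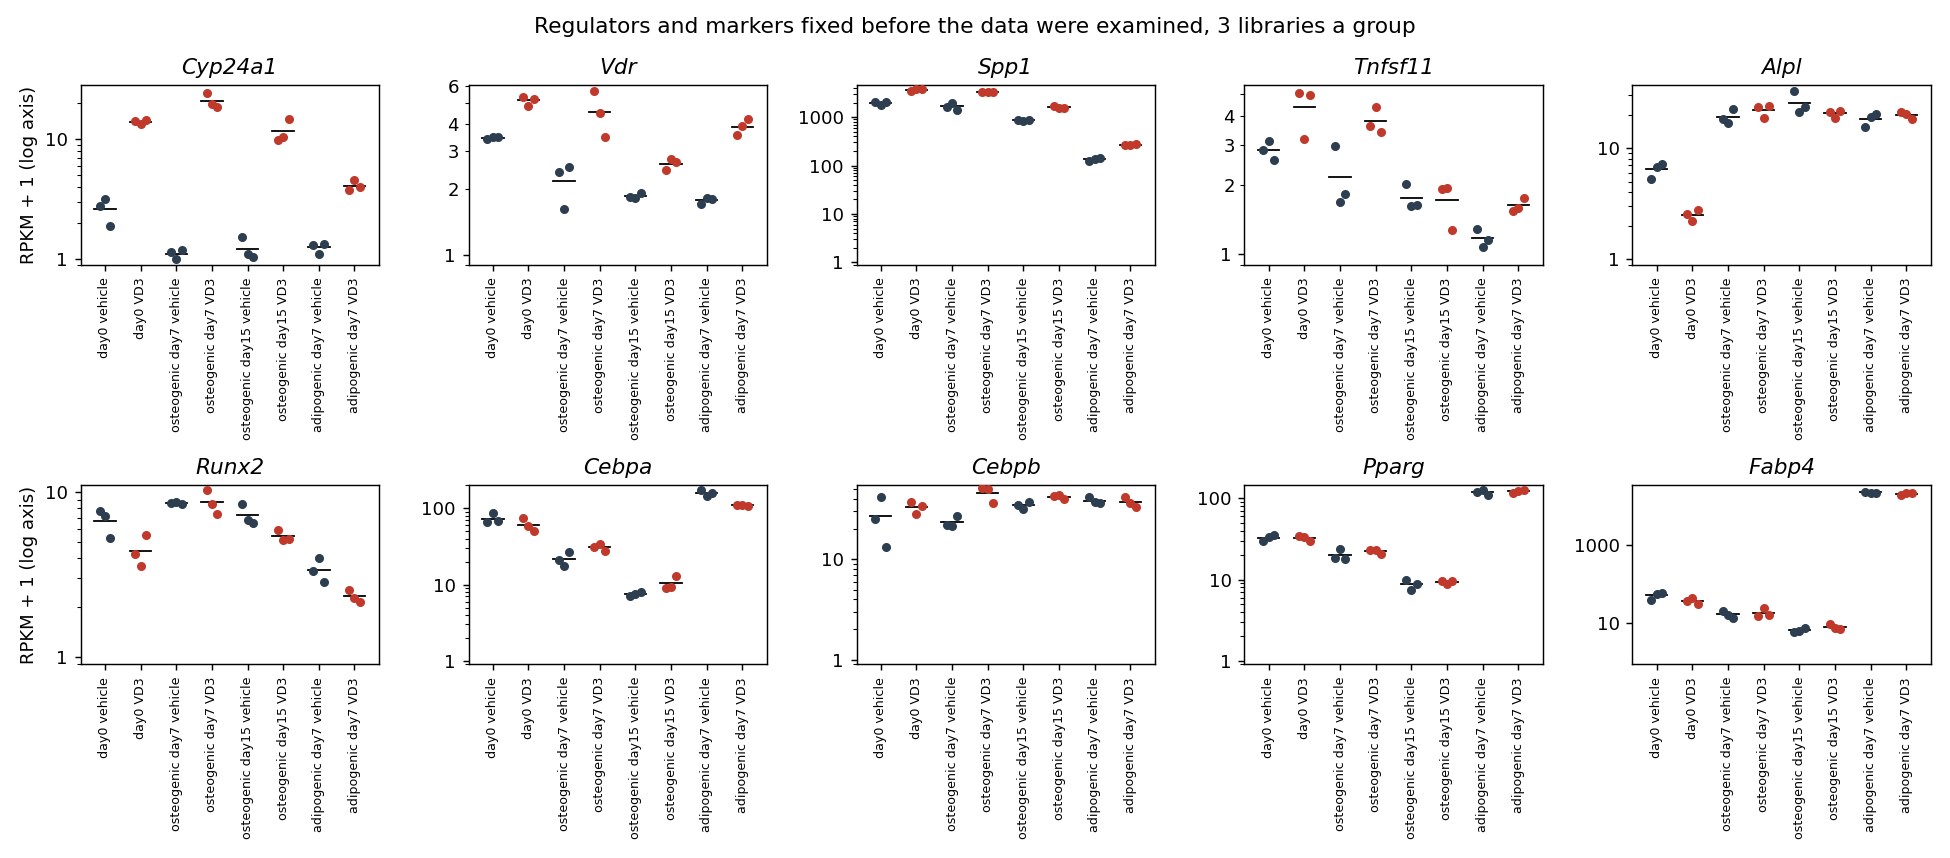
RPKM + 1 on a log axis of 10 genes fixed before the data were examined, 1 point a library and a bar at the mean of 3, vehicle dark and VD3 red. Cyp24a1 rose with VD3 in all 4 states, from 1.62 ± 0.661 to 13.0 ± 0.576 RPKM at day 0.

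VD3 for 24 hours was compared with vehicle in each state, to ask how its effect depends on cell fate. At day 0 the methyltransferase Inmt rose from 1.34 ± 0.585 to 143 ± 8.88 RPKM, the collagenase Mmp13 from 13.7 ± 1.38 to 214 ± 20.1 and Cyp24a1 from 1.62 ± 0.661 to 13.0 ± 0.576. Cib2 (34.6 ± 2.96 against 2.39 ± 0.392 with vehicle), the keratin Krt17 (10.5 ± 1.87 against 0.544 ± 0.273) and Gdpd5 (9.81 ± 0.222 against 0.678 ± 0.0586) were the other largest rises. Known vitamin D targets rose: 7 rose and 0 fell of 13 (9 and 0 adjusted over the list alone), adjusted p = 0.000227. Enpp3 was at 28.1 ± 2.20 against 5.58 ± 0.677. Spp1, itself a target in bone cells, rose to 3684 ± 248 from 1971 ± 136. The largest falls were the small matrix proteoglycans Omd (8.12 ± 0.372 against 64.3 ± 4.10) and Aspn (4.49 ± 0.926 against 22.2 ± 2.95) and the matricellular protein Nov (30.1 ± 0.801 against 150 ± 5.78). The others were Csrp2 (33.6 ± 5.497 against 158 ± 10.3), Il1rn (23.8 ± 2.78 against 105 ± 8.19) and Olfml3 (25.2 ± 2.09 against 109 ± 7.48). Alpl fell to 1.52 ± 0.283 from 5.44 ± 0.992.

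Of the proliferation genes 0 rose and 23 fell of 26 (0 and 25 adjusted over the list alone), with adjusted p = 2.35e-05. Rrm2 (10.2 ± 1.04 against 27.6 ± 4.21 RPKM) fell most. Of the cholesterol synthesis genes 0 rose and 12 fell of 17 (0 and 15 adjusted over the list alone), with adjusted p = 0.000543. Insig1 (102 ± 3.00 against 199 ± 8.05) and Idi1 (26.1 ± 1.48 against 50.3 ± 2.52) fell. Of the matrix genes 4 rose and 12 fell of 25 (6 and 14 adjusted over the list alone), with adjusted p = 0.0475. The first in size were Col6a2 (15.1 ± 0.636 against 66.0 ± 2.40) and Col6a1 (66.2 ± 6.73 against 226 ± 8.05). Smooth muscle and pericyte markers moved with them: 0 rose and 6 fell of 10 (0 and 8 adjusted over the list alone), adjusted p = 0.0397. Vdr (4.13 ± 0.254 against 2.46 ± 0.0407) rose and Runx2 (3.41 ± 0.963 against 5.72 ± 1.26) fell, but Vdr in both groups, and Runx2 and Alpl with VD3, lay under the vehicle background median. Tnfsf11 (3.40 ± 1.07 against 1.84 ± 0.274, adjusted p = 0.0856), Fabp4 (36.7 ± 6.56 against 51.0 ± 10.4, 0.0813), Cebpa (60.2 ± 13.2 against 72.4 ± 11.7, 0.223), Cebpb (32.0 ± 4.59 against 25.7 ± 14.5, 0.204) and Pparg (31.4 ± 2.22 against 32.0 ± 2.74, 0.884) did not pass the test.

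At day 0, 840 genes were higher and 2328 lower with VD3 (137 and 503 at 2-fold or more), and the median of all genes was -0.27 log2. The background median was 2.77 ± 2.07 RPKM with VD3 and 4.21 ± 0.721 with vehicle. The higher share of 26.5% became 64.1% with median-ratio rescaling and 57.7% with quantile normalization (median shifts 0.19 and 0.33), and 1273 were higher and 1280 lower after the GC-matched subtraction, 1439 and 663 after the equal one and 837 and 1132 with a filter at 5 RPKM. Lower genes numbered 6112 without VD3 replicate 1, 930 without VD3 replicate 2, 1418 without vehicle replicate 2 and 1300 without vehicle replicate 3. Median-ratio rescaling ended the calls of the proliferation (0 rose and 10 fell, adjusted p = 0.0687), cholesterol (0 and 3, 0.351) and matrix (0.487) lists. The narrow fit ended the target (0.0777) and matrix (0.464) calls, and with the equal subtraction the target call alone held (0.0479). The matrix call also ended after the GC-matched subtraction (0.0510) and without VD3 replicate 1 (0.186) or 3 (0.0783) or vehicle replicate 1 (0.0709) or 2 (0.0546). The smooth muscle call ended without the same libraries (0.0900, 0.0783, 0.0709 and 0.0546), with both rescalings (0.0687 and 0.0947) and in the narrow fit (0.0783). Vdr (log2 0.57) lost its call without vehicle replicate 1 (0.56), 2 (0.57) or 3 (0.57) or VD3 replicate 2 (0.61) or 3 (0.55), and Runx2 (log2 -0.61) without vehicle replicate 1 (-0.50) or 2 (-0.55) or VD3 replicate 2 (-0.47). Some passed without 1 library: Cebpb (vehicle replicate 2, 0.85), Cebpa (VD3 replicate 1, -0.43), Tnfsf11 (VD3 replicate 2, 0.82) and Fabp4 (vehicle replicate 1, -0.64).

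On osteogenic day 7, VD3 raised Cyp24a1 to 19.8 ± 3.00 RPKM from 0.109 ± 0.0960 and Inmt to 76.6 ± 10.8 from 1.37 ± 0.453. The protease inhibitor Slpi (11.04 ± 2.65 against 0.241 ± 0.211 with vehicle), the thyroid hormone-activating deiodinase Dio2 (193 ± 7.06 against 25.1 ± 2.32), Mmp13 (298 ± 43.7 against 48.0 ± 8.47) and Klhl33 (7.50 ± 1.94 against 0.433 ± 0.381) were the other largest rises. Of the known vitamin D targets 9 rose and 0 fell of 13 (9 and 0 adjusted over the list alone), with adjusted p = 0.000122, and Enpp3 rose to 21.7 ± 3.57 from 3.98 ± 0.142. Vdr (3.55 ± 1.09 against 1.18 ± 0.485), Spp1 (3255 ± 21.1 against 1655 ± 292), Tnfsf11 (2.81 ± 0.515 against 1.16 ± 0.692) and Cebpb (45.2 ± 8.59 against 22.4 ± 2.95) rose. Bone sialoprotein went the other way, with Ibsp at 89.1 ± 15.6 against 264 ± 11.9. The enzyme Has2 (33.1 ± 3.85 against 103 ± 12.5), Csrp2 (188 ± 21.01 against 542 ± 101), Lrrc17 (4.14 ± 1.41 against 13.2 ± 0.709) and the urokinase gene Plau (12.5 ± 1.24 against 35.6 ± 4.43) were also among the largest falls.

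Proliferation genes fell here too: 0 rose and 20 fell of 26 (0 and 22 adjusted over the list alone), adjusted p = 2.24e-08. Ccna2 (14.7 ± 2.14 against 30.1 ± 4.14 RPKM) fell most. Of the cholesterol synthesis genes 0 rose and 11 fell of 17 (0 and 11 adjusted over the list alone), with adjusted p = 3.98e-06. Examples are Fdps (23.1 ± 2.64 against 41.3 ± 2.77) and Cyp51 (67.1 ± 6.39 against 112 ± 5.63). Of the matrix genes 2 rose and 7 fell of 25 (2 and 13 adjusted over the list alone), with adjusted p = 0.00337. Tnc (42.7 ± 5.45 against 96.5 ± 3.68) fell while Fn1 (431 ± 43.2 against 221 ± 15.3) rose. Smooth muscle and pericyte markers were lower as a list: 0 rose and 3 fell of 10 (0 and 5 adjusted over the list alone), adjusted p = 0.0101. Alpl (21.1 ± 2.88 against 18.1 ± 2.92, adjusted p = 0.655), Runx2 (7.70 ± 1.47 with VD3 against 7.62 ± 0.101, adjusted p of 1), Cebpa (29.9 ± 3.12 against 20.7 ± 4.59, 0.0600), Pparg (21.2 ± 1.41 against 19.1 ± 3.08, 0.656) and Fabp4 (17.7 ± 4.94 against 16.2 ± 3.68, 0.902) did not pass the test. In all, 614 genes were higher and 496 lower (123 and 53 at 2-fold or more), and 397 and 321 without vehicle replicate 2. The higher share of 55.3% became 39.0% (298 and 467 genes) with median-ratio rescaling, which, like quantile normalization, ended the matrix call (adjusted p = 0.233 and 0.166). So did the equal subtraction (0.270), and the narrow fit ended the target (0.0726), matrix (0.0602) and smooth muscle (0.264) calls. Cebpb (log2 0.97) lost its call without vehicle replicate 1 (0.94) or 2 (0.91) or VD3 replicate 1 (0.88) or 2 (0.90). The call of Tnfsf11 (log2 0.85) was lost with both rescalings and without vehicle replicate 2 (0.70) or 3 (0.76) or VD3 replicate 1 (0.88), 2 (0.75) or 3 (0.93). Cebpa passed without vehicle replicate 3 (0.68).

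On osteogenic day 15 the largest rises with VD3 were Cyp24a1 (10.7 ± 2.57 against 0.218 ± 0.266 RPKM with vehicle), Dio2 (119 ± 14.5 against 19.1 ± 0.983), and Inmt (14.6 ± 2.86 against 2.29 ± 0.768). Slpi (7.42 ± 1.87 against 1.35 ± 0.449), the galectin Lgals2 (12.6 ± 4.79 against 3.53 ± 0.433) and Gzme (7.16 ± 5.47 against 1.48 ± 0.175) followed. Ibsp fell to 238 ± 14.3 from 596 ± 40.1, the protease Prss23 to 33.2 ± 1.07 from 68.3 ± 3.61, and Lrrc17 to 4.88 ± 0.751 from 10.6 ± 1.58. Tnc fell to 56.5 ± 3.89 from 104 ± 6.62 and Serpinb1a to 5.54 ± 0.661 from 10.8 ± 2.12. Of the known vitamin D targets 5 rose and 0 fell of 13 (6 and 0 adjusted over the list alone), with adjusted p = 0.000658. They include Enpp3 (6.51 ± 0.401 against 1.78 ± 0.175) and Mmp13 (151 ± 6.86 against 65.0 ± 5.16). Of the matrix genes 0 rose and 6 fell of 25 (0 and 9 adjusted over the list alone), with adjusted p = 0.000625. Among them were the thrombospondin Thbs1 (97.1 ± 2.40 against 144 ± 7.07) and periostin, Postn (197 ± 5.82 against 266 ± 22.0). Of the osteoblast genes 1 rose and 2 fell of 21 (1 and 7 adjusted over the list alone), with adjusted p = 0.0255. Beside Ibsp, the sphingomyelinase Smpd3 (1.26 ± 0.287 against 3.06 ± 0.535) fell, and Spp1 (1594 ± 112 against 854 ± 17.3) rose. Proliferation genes (0 called by limma over all genes, 1 lower adjusted over the list alone and 8 lower at unadjusted p < 0.05, of 26) and cholesterol synthesis genes (0 called by limma either way and 3 lower at unadjusted p < 0.05, of 17) were lower as lists in camera, with adjusted p = 0.000831 and 0.0332.

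Vdr (1.62 ± 0.163 against 0.863 ± 0.0445 RPKM, adjusted p = 0.450), Runx2 (4.40 ± 0.399 against 6.28 ± 1.08, 0.634), Cebpa (9.43 ± 2.17 against 6.54 ± 0.492, 0.433) and Alpl (19.6 ± 1.62 against 24.7 ± 5.88, 0.903) did not pass the test, nor did Cebpb (40.99 ± 1.63 against 33.6 ± 2.86), Pparg (8.42 ± 0.458 against 7.74 ± 1.246), Fabp4 (7.15 ± 1.18 against 5.79 ± 0.781) and Tnfsf11 (0.715 ± 0.377 against 0.760 ± 0.229), each with an adjusted p of 1. In all, 111 genes were higher and 52 lower (26 and 3 at 2-fold or more). The higher share of 68.1% became 82.6% with median-ratio rescaling (71 and 15 genes), which ended the matrix (adjusted p = 0.144), proliferation (0.113) and cholesterol (0.664) calls. Higher genes numbered 72 without VD3 replicate 1, and lower genes 21 without vehicle replicate 1, 29 without vehicle replicate 3, 22 without VD3 replicate 1 and 32 without VD3 replicate 2. No list call held in the narrow fit (lowest 0.131), and with the equal subtraction the target call alone did (0.00510). The osteoblast call ended without vehicle replicate 3 (adjusted p = 0.0514) and with quantile normalization (0.141). The cholesterol call ended without vehicle replicate 3 (0.147) or VD3 replicate 1 (0.0761) or 2 (0.0597). Without vehicle replicate 1, Lgals2 (1.45 log2), Gzme (1.54), Lrrc17 (-0.95), Serpinb1a (-0.75) and Postn (-0.38) no longer passed. The same happened to Gzme, Lrrc17, Serpinb1a and Postn without vehicle replicate 2 (1.55, -0.89, -0.78 and -0.41) and to Gzme without vehicle replicate 3 (1.46). Without VD3 replicate 1 it happened to Lgals2 (1.47), Lrrc17 (-0.90), Serpinb1a (-0.77) and Postn (-0.43), without VD3 replicate 2 to Serpinb1a (-0.85) and Postn (-0.41), and without VD3 replicate 3 to Lgals2 (1.28), Lrrc17 (-0.96) and Postn (-0.45).

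On adipogenic day 7, VD3 raised Inmt to 29.0 ± 6.04 RPKM from 0.177 ± 0.169, Mgp to 93.1 ± 20.1 from 13.8 ± 3.38 and the matricellular Smoc2 to 10.2 ± 0.342 from 1.29 ± 0.362. Elfn1 (6.12 ± 0.923 against 0.554 ± 0.0515 with vehicle), Ttc39c (20.9 ± 3.04 against 3.93 ± 0.593) and the collagen Col16a1 (8.38 ± 0.322 against 1.18 ± 0.246) were the other largest rises. Ibsp, at 104 ± 7.89 RPKM in vehicle-treated adipogenic cells, fell to 3.23 ± 0.404. Omd (9.88 ± 1.49 against 83.1 ± 2.59), the tenascins Tnn (4.30 ± 0.476 against 20.02 ± 1.76) and Tnc (3.97 ± 0.319 against 16.4 ± 1.03), Aspn (3.56 ± 1.08 against 13.8 ± 0.337) and Has2 (1.47 ± 0.777 against 6.54 ± 0.275) were the other largest falls. Of the known vitamin D targets 6 rose and 1 fell of 13 (7 and 1 adjusted over the list alone), with adjusted p = 0.00571. Examples are Cyp24a1 (3.10 ± 0.429 against 0.252 ± 0.135), Enpp1 (3.08 ± 0.706 against 0.772 ± 0.0730) and Enpp3 (1.98 ± 0.310 against 0.339 ± 0.259). Vdr (2.89 ± 0.318 against 0.779 ± 0.0533) and Spp1 (266 ± 8.45 against 134 ± 11.3) rose. Of the matrix genes 3 rose and 8 fell of 25 (7 and 9 adjusted over the list alone). They include the collagen Col12a1 (12.7 ± 0.513 against 37.5 ± 5.09) and Postn (36.6 ± 2.45 against 98.6 ± 5.41). The list test had adjusted p = 0.0952 with an estimated correlation and 0.00120 with a preset one, and 0.0343 without VD3 replicate 3 and 0.0382 without vehicle replicate 1. Of the proliferation genes 0 rose and 1 fell of 26 (0 and 1 adjusted over the list alone), and the list was called lower (adjusted p = 0.00571, and 0.276 with median-ratio rescaling).

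None of the 21 adipocyte genes was called by limma after VD3, over all genes or adjusted over the list alone, and camera gave adjusted p = 0.509. Only 1 of the 21 had an unadjusted p < 0.05. Pparg (122 ± 5.46 against 119 ± 8.53 RPKM), Fabp4 (20617 ± 1512 against 22526 ± 902), Alpl (18.9 ± 1.28 against 17.3 ± 2.58) and Cebpb (35.8 ± 4.32 against 37.3 ± 2.82) each had an adjusted p of 1. Cebpa (108 ± 2.98 against 157 ± 15.0, adjusted p = 0.115), Runx2 (1.33 ± 0.207 against 2.38 ± 0.569, 0.179) and Tnfsf11 (0.633 ± 0.116 against 0.170 ± 0.107, 0.691) did not pass the test either. In all, 318 genes were higher and 121 lower (82 and 31 at 2-fold or more), and 178 and 100 with median-ratio rescaling. The vitamin D target call ended among genes with a mean of at least 20 RPKM (adjusted p = 0.165), and neither list call held in the narrow fit (0.192 for both) or with the equal subtraction (lowest 0.0709).

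**Figure D3:**
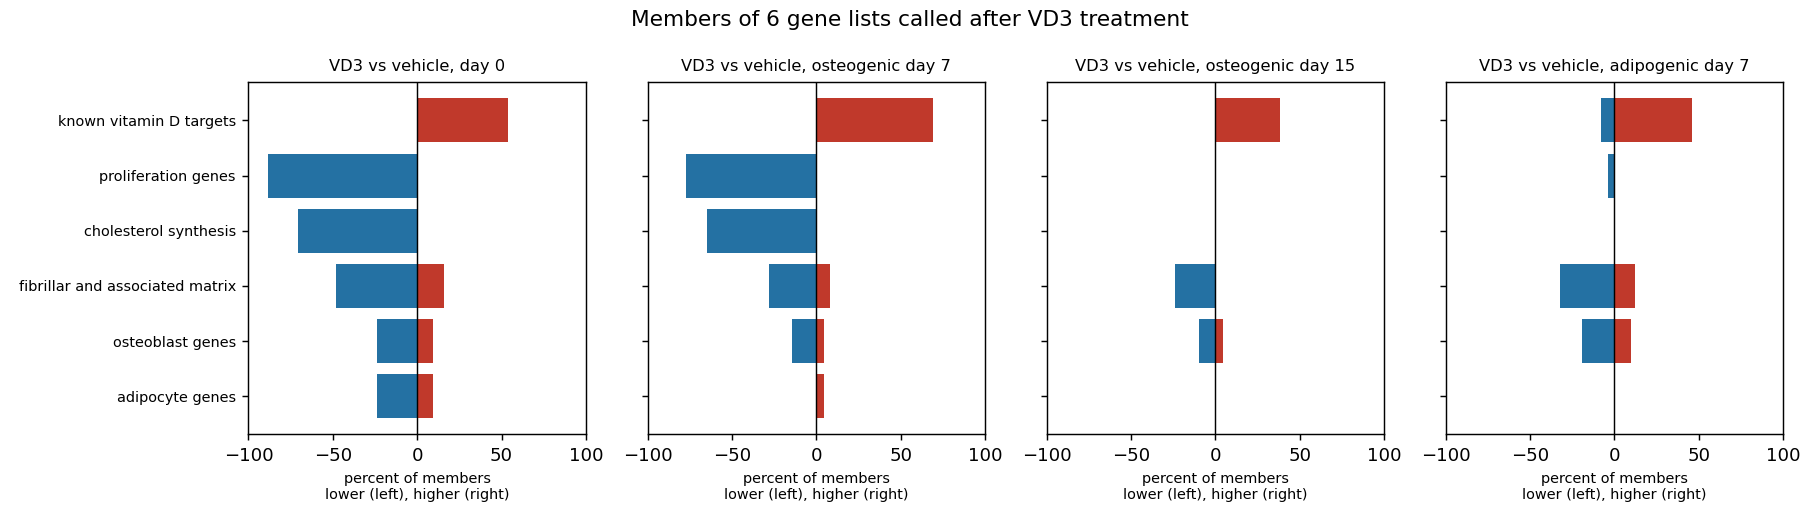
Percent of the measured members of 6 gene lists that were called higher (right, red) or lower (left, blue) with VD3, in each of the 4 states. Proliferation genes fell in 23 of 26 at day 0 and 20 of 26 on osteogenic day 7; with median-ratio rescaling the first count is 10.

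The responses to VD3 shared genes across states, whose libraries are separate. Day 0 and osteogenic day 7 had 352 higher genes in common (24.4 expected if independent), 313 lower (54.7) and 9 opposite. Osteogenic day 7 and adipogenic day 7 had 166 higher (9.25), 40 lower (2.84) and 18 opposite. In all 4 states 58 genes were higher (0.00194 expected) and 18 lower (0.000774). These became 28 and 5 with median-ratio rescaling, 42 and 11 with quantile normalization, 42 and 7 with plain empirical Bayes, 28 and 8 with the equal subtraction and 23 and 4 in the narrow fit. Without osteogenic day 15 vehicle replicate 1 or 2 the 18 were 10 or 11, and without VD3 replicate 1, 2 or 3 of that day 9, 11 or 10. Without any 1 library Cyp24a1, Inmt, Krt17, Enpp1, Enpp3 and Spp1 stayed higher in each state, and Ibsp, Tnc, Nov and Plau lower.

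The difference in VD3 effect between states was tested directly. Mmp13 rose by 3.87 log2 at day 0 and 2.62 on osteogenic day 7, and changed by -0.59 on adipogenic day 7, so that the adipogenic effect differed by -4.46 (adjusted p = 1.53e-13) and -3.20 (7.07e-11). Its effect on osteogenic day 15 was 1.21, a difference of -2.66 from day 0 (2.89e-09). Ibsp fell more in adipogenic cells than on osteogenic day 7, by -3.07 log2 (1.69e-11). Slpi rose by 3.27 on osteogenic day 7 and changed by 0.03 at day 0, a difference of 3.24 (3.37e-05). Omd fell by 2.84 at day 0 and changed by -0.55 on osteogenic day 7, a difference of 2.28 (1.62e-06). For proliferation genes the VD3 effect in adipogenic cells, set against osteogenic day 7, was higher for 6 and lower for 0 of 26 (15 and 0 adjusted over the list alone), with camera adjusted p = 2.24e-06 and 0.00373 with median-ratio rescaling (0.358 with the equal subtraction). For cholesterol synthesis genes these were 6 and 0 of 17 (12 and 0 adjusted over the list alone). Their adjusted p was 4.07e-05, and 0.136 with that rescaling. All 26 proliferation genes were lower in adipogenic vehicle cells, where the log2 scale understates changes of low genes. A weaker effect cannot be told from that limit.

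**Figure D4:**
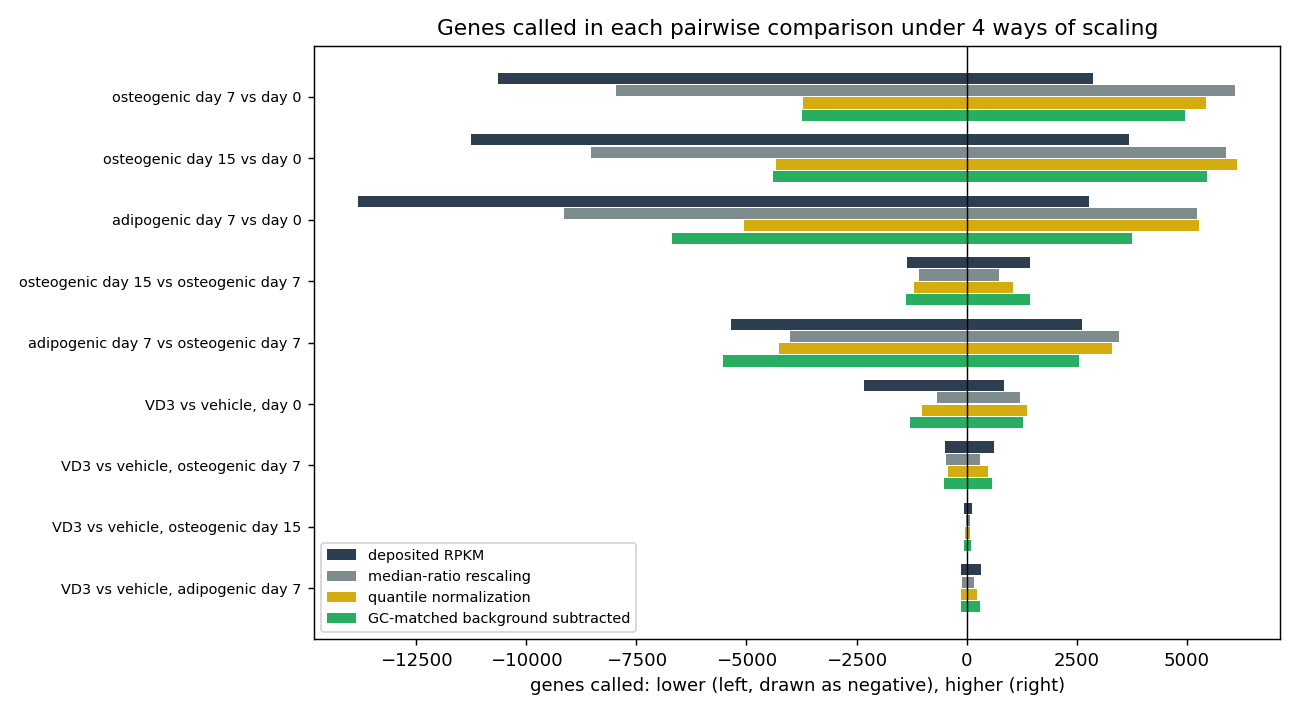
Genes called lower (left, drawn as negative) and higher (right) in the 9 pairwise comparisons, with the deposited RPKM, 2 rescalings and a GC-matched background subtraction. On osteogenic day 7 against day 0 the deposited values give 2874 higher and 10636 lower genes, and the subtraction gives 4967 and 3745.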

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

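Tests on other unexpressed genes, on reads per kilobase and on the day 0 libraries as a set were chosen only after the results were seen, as was a spread named below. Listed first are direct tests of differences between states in VD3 effect.

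VD3 acted differently on osteogenic day 7 than at day 0 on 539 genes, led by Slpi (3.24), Omd (2.28), Tnfsf4 (2.16), Ttc39c (-2.45), Cib2 (-1.48) and Rsad2 (-1.41), with the log2 difference in brackets. On osteogenic day 15 the difference from day 0 covered 600 genes, led by Omd (2.42), Car3 (2.26), the background gene Olfr15 (2.06), Inmt (-3.70), Mmp13 (-2.66) and Ttc39c (-2.57). On adipogenic day 7 it covered 732 genes, led by Defb13 (2.64), Angptl1 (2.34), the background gene Olfr15 (2.08), Mmp13 (-4.46), Cib2 (-3.04) and Ibsp (-2.62). Between adipogenic and osteogenic day 7, 384 genes differed, led by Ttc39c (2.19), Col16a1 (1.87), Elfn1 (1.87), Mmp13 (-3.20), Ibsp (-3.07) and Slpi (-2.92). These 4 counts were 295, 295, 407 and 177 with median-ratio rescaling and 142, 385, 514 and 196 in the narrow fit.

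By direction, the VD3 effect was more positive for 391 and more negative for 148 genes on osteogenic day 7 than at day 0, for 347 and 253 on osteogenic day 15, for 519 and 213 on adipogenic day 7, and for 204 and 180 on adipogenic against osteogenic day 7. The median of all genes in the 3 differences from day 0 was 0.32, 0.27 and 0.31 log2; median-ratio rescaling shifted it by -0.27, -0.19 and -0.25 and quantile normalization by -0.42, -0.37 and -0.40. The more positive share went from 72.5, 57.8 and 70.9% to 22.7, 21.02 and 27.5% with the first and 45.2, 39.9 and 41.3% with the second. For osteogenic day 7 the count of 539 changed most without day 0 VD3 replicate 1 (2300), VD3 replicate 2 (267), vehicle replicate 2 (316), vehicle replicate 3 (344) and osteogenic day 7 vehicle replicate 1 (288), vehicle replicate 2 (247), VD3 replicate 1 (265). For osteogenic day 15 it was day 0 VD3 replicate 1 (1994) and osteogenic day 15 VD3 replicate 1 (375), and for adipogenic day 7 day 0 VD3 replicate 1 (2497), VD3 replicate 2 (484) and adipogenic day 7 vehicle replicate 1 (460), VD3 replicate 2 (472).

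Tnfsf4 lost its call without day 0 vehicle replicate 3 (1.94), osteogenic day 7 vehicle replicate 1 (2.13) or VD3 replicate 1 (2.02). Rsad2 lost it without day 0 vehicle replicate 1 (-1.39), 3 (-1.29), VD3 replicate 2 (-1.36) or 3 (-1.34). It also lost it without osteogenic day 7 vehicle replicate 2 (-1.24), 3 (-1.38), VD3 replicate 1 (-1.50) or 3 (-1.22). Olfr15 on osteogenic day 15 lost it without day 0 vehicle replicate 2 (1.96), 3 (2.00), day 0 VD3 replicate 2 (1.60), osteogenic day 15 vehicle replicate 1 (1.84), 3 (1.98), osteogenic day 15 VD3 replicate 1 (1.74), and on adipogenic day 7 without day 0 vehicle replicate 2 (1.98), 3 (2.02), day 0 VD3 replicate 2 (1.62), adipogenic day 7 vehicle replicate 2 (1.94), 3 (2.00), adipogenic day 7 VD3 replicate 1 (1.82). Defb13 lost it without day 0 vehicle replicate 1 (2.06), day 0 VD3 replicate 2 (2.50), adipogenic day 7 vehicle replicate 1 (2.58), 2 (2.36), adipogenic day 7 VD3 replicate 1 (2.33), 2 (2.63).

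Other splits of the same samples were counted. For differences of VD3 effects, 100 relabellings of treated and vehicle libraries within both states were drawn, the real one included. As many genes as the real split came in 5 of 100 on osteogenic day 7 against day 0 (real 539, highest other 2284). It was 7 on osteogenic day 15 (600, 1004) and 6 on adipogenic day 7 (732, 996). For adipogenic against osteogenic day 7 it was 4 (384, 1021). The other splits as large (4, 6, 5 and 3) kept or swapped the libraries of the second state whole and so hold its VD3 effect. They do not test whether the effects differ, so these 4 shares say nothing about chance. This was judged after the counts were seen. For the 9 pairwise comparisons the 6 libraries make 10 splits, too few for a share under 0.05. The others mix both groups, which widens the spread, so their few calls say nothing about chance. Genes called and the highest other split were 13510 and 1 (osteogenic day 7 against day 0), 14952 and 1 (osteogenic day 15), 16589 and 1 (adipogenic day 7), 2813 and 0 (osteogenic day 15 against 7), 7977 and 0 (adipogenic against osteogenic day 7), and for VD3 3168 and 122 (day 0), 1110 and 1 (osteogenic day 7), 163 and 0 (osteogenic day 15) and 439 and 1 (adipogenic day 7).

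In 5 of 6 day 0 libraries genes of unexpressed receptor families had 3.39 to 4.95 RPKM. The excess over the other 19 libraries was 9.12-fold in RPKM and 2.13-fold in reads per kilobase, and the 5 had fewer reads. At the closest depths, day 0 VD3 replicate 1 had 4.45 RPKM and 49.0 reads per kilobase, and osteogenic day 7 vehicle replicate 3 0.394 and 4.64. A smaller number of reads in the denominator is argued against as the whole cause, since in reads per kilobase each of the 5 (33.2 to 49.0) lay above each of the 19 (4.64 to 27.9). Reads from genomic DNA may be a source. In median RPKM, which fewer reads also raise, 10937 other unexpressed genes were 5.24-fold higher. Neither this nor the X chromosome decides. The X to autosome ratio was 0.715 (0.640 to 0.747 in the 5, 0.174 to 0.772 in the 19). The cells express Y-linked Ddx3y (median 83.9 RPKM). A state of undifferentiated cells also stays open, since 1 of the 6 day 0 libraries, which alone decides nothing, lay in the range of the differentiated ones.

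At day 0 more genes were lower than higher with VD3 (73.5% of calls). A candidate explanation is one treated library with a low background, and another is lower expression of more genes after VD3. Without day 0 VD3 replicate 2, 61.0% of calls were lower, past the bound of 60% written beforehand as counting against the first. The excess is within the SD of 8.89 points over the other 5 libraries left out (66.9 to 87.1%), a spread chosen after the value was seen, so these explanations cannot be told apart. After GC-matched subtraction 50.1% were lower, against a bound of at most 50% for excluding the second.

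Adipocyte genes were higher at day 0 than on osteogenic day 7. Background reads at day 0 may account for part of this: 8 of 19 tested adipocyte genes were still lower after the GC-matched subtraction, between the bounds of fewer than 6 and at least 11. For a change with osteogenic medium, the median difference between the osteogenic day 7 VD3 libraries and day 0 VD3 replicate 2, which has a low background, was -0.12 log2, between the bounds of -0.5 and 0. The list was called lower there (0 and 6 of 21, adjusted p = 0.00983), against 1 library and with no bound set for it. Neither bounded test separates these explanations, because each value lies between its bounds.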

How the results depend on the processing

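Largest transcript, both background subtractions, means of at least 20 RPKM and the lone day 0 library were chosen after seeing the data. The cause was not tested unless stated. Counts are higher and lower genes, given where they moved by more than 1.5 times. In the 335 named gene results, alternatives set beforehand left direction and side of the threshold unchanged in 4826 of 5008, with 144 no longer called, 28 newly called and 10 reversed. The others gave 1271 of 1326, 31, 8 and 16, of which 4 are 0. Reversed (turned) values may be uncalled. Of the 81 list calls, 37 held with median-ratio rescaling, 54 with quantile normalization, 60 with GC-matched subtraction, 19 with the equal subtraction, 30 of the 61 tested there among genes with a mean of at least 20 RPKM, 32 in the fit on only the libraries compared, 78 with a replicate term, and 37 of 45 with VD3-treated libraries in place of vehicle, where 1 turned. Of the list calls not in the report, 3 were left out after their values without single libraries were seen. For VD3 at day 0, glycolysis and oxidative phosphorylation genes were called higher (adjusted p = 0.0323 for both), but not without VD3 replicate 2 (0.147) or vehicle replicate 1 (0.0638) or 2 (0.0546). For VD3 on osteogenic day 15, osteocyte genes were called lower (0.0341), but not without VD3 replicate 1 (0.0784) or 3 (0.0603) or vehicle replicate 2 (0.121) or 3 (0.0514). Of calls never described there, 2 also ended. Wnt targets on osteogenic day 7 against day 0 were called higher (0.0487), but not without osteogenic day 7 vehicle replicate 1 (0.0584) or 3 (0.0589) or day 0 vehicle replicate 1 (0.0584), 2 (0.0550) or 3 (0.0561). Glucocorticoid-responsive genes between osteogenic days were called lower (0.0417), but not without osteogenic day 15 vehicle replicate 3 (0.0679). A preset correlation called 137 lists. Pairing by replicate number stays open (0 comparisons have a correlation over 0.1 for all 3 numbers). With a replicate term osteogenic day 7 against day 0 gave 2854 and 10598.

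With median-ratio rescaling, osteogenic day 7, osteogenic day 15 and adipogenic day 7 against day 0 gave 6103, 5887 and 5223 higher and the last 9136 lower; osteogenic day 15 against 7 gave 740 higher. VD3 gave 680 lower at day 0, 298 higher on osteogenic day 7, 71 and 15 on osteogenic day 15 and 178 higher on adipogenic day 7. The differences of VD3 effects gave 295, 295, 407 and 177 genes. Spp1 on osteogenic day 7 turned to 0.17. With quantile normalization the comparisons to day 0 gave 5431 and 3716, 6128 and 4334, and 5273 and 5065, and VD3 1367 and 1004 at day 0 and 29 lower on osteogenic day 15. Vdr against day 0 turned to 0.49, 0.35 and 0.17 on osteogenic day 7, osteogenic day 15 and adipogenic day 7, and Tnfsf11 to 0.68 and 0.49 on the osteogenic days.

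With the equal background subtracted, the comparisons to day 0 gave 8710 and 1451, 8538 and 1774, and 5511 and 3137, osteogenic day 15 against 7 893 and 856, and VD3 1439 and 663, 319 and 320, 56 and 26, and 207 higher in the 4 states. Adipogenic against osteogenic day 7 in VD3 effect gave 225. Reversed against day 0 were Vdr (0.86, 0.61 and 0.11 on osteogenic day 7, osteogenic day 15 and adipogenic day 7), Tnfsf11 (0.82 and 0.49 on the osteogenic days), Cyp24a1 (0.11 on osteogenic day 15) and Runx2 (0.15 on adipogenic day 7). Tnfsf11 on adipogenic day 7 and Cyp24a1 on osteogenic and adipogenic day 7 became 0. With the background matched on GC content the comparisons to day 0 gave 4967 and 3745, 4407 lower and 6696 lower, VD3 at day 0 1273 and 1280, and shared differentiation calls 5008 in place of 10262 (6113 at 2-fold or more). Tnfsf11 turned to 0.88 and 0.58 on the osteogenic days and became 0 on adipogenic day 7.

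Among genes with a mean of at least 20 RPKM, where fewer genes are tested, the counts were 1493 and 394, 1800 and 609, 1259 and 1481 against day 0, 891 and 654 between osteogenic days, 983 and 1812 between fates, 487 and 420 for VD3 at day 0, 255, 54 and 174 higher for VD3 in the other states, and 272 and 412 for osteogenic and adipogenic day 7 minus day 0. Among VD3-treated libraries with day 0 VD3 replicate 2 as the lone day 0 library, which changes the arm and uses fewer samples, they were 1471 and 530, 2304 and 1275, and 3298 lower, and Speer7-ps1, Hrnr and Cyp24a1 on osteogenic day 7 turned to 0.49, 0.50 and 0.62. The stricter filter, which tests fewer genes, gave 2768, 3369 and 5608 lower against day 0 and 1132 lower for VD3 at day 0. VD3-treated libraries in place of vehicle gave 5231, 6895 and 6585 lower against day 0. There Cyp24a1 turned to 0.56 (osteogenic day 7 against day 0), -0.85 (osteogenic day 15 against 7) and -2.34 (adipogenic against osteogenic day 7), and Cebpb to -0.32 in the last. A pseudocount of 0.1 gave 1003 lower for VD3 at day 0 and 284 genes for osteogenic day 7 minus day 0. The narrow fit, with fewer samples, gave for VD3 558 lower, 280 and 192, 45 and 18, and 74 lower. For the differences it gave 142, 385 and 196 (adipogenic against osteogenic day 7). Plain empirical Bayes gave 31 lower for VD3 on osteogenic day 15.

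Leave-one-out ranges, higher then lower: against day 0, 2498 to 2696 and 9902 to 10173 (osteogenic day 7), 3332 to 3470 and 10581 to 10924 (osteogenic day 15), 2595 to 2683 and 13048 to 13281 (adipogenic day 7); between osteogenic days 1020 to 1250 and 1045 to 1173; between fates 2326 to 2482 and 4910 to 5033. For VD3 they were 595 to 905 and 930 to 6112 (day 0), 397 to 593 and 321 to 525 (osteogenic day 7), 72 to 87 and 21 to 37 (osteogenic day 15), and 235 to 246 and 86 to 98 (adipogenic day 7), and for differences of VD3 effects 247 to 2300, 375 to 1994, 460 to 2497 and 264 to 381. Depth limits genes near 0.0642 to 0.421 RPKM (3 reads on 1 kilobase by library).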

Other observations

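Between osteogenic day 7 and day 0 the lists of endothelial (adjusted p = 0.654), macrophage (0.654), osteoclast (0.933) and erythroid (0.560) markers were not called by camera.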
